A study of Mus musculus with 4 samples.

How the data were processed

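The data are 4 Omni-ATAC-seq libraries from mouse cells, 1 of OPCs and 1 of O1-sorted OLs from each of the epiblast stem cell lines 129O1 and EpiSC5. Per the labels' protocols, OPCs were grown with bFGF and PDGFA at 20 ng/mL each, sorted on CD140a and NG2 after 4 passages and expanded again. Transposition was done on nuclei of 50000 cells for 30 min at 37 °C, and single-end 50 bp reads were sequenced, with a stated yield of 100 M reads per sample. The labels name the strains 129SvEv and 129S1/SvImJ, and only the order of the names ties a strain to a line, so the lines are not assigned to strains here. Per the submitters' processing notes, Trim Galore 0.3.1, Bowtie2 2.3.2, Picard and MACS2 were used with the genome build mm10. The MACS2 version, the significance threshold, the handling of duplicates, any shift of the reads for the Tn5 cut and the fragment extension are not given in the sources used here.

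The deposited files are MACS2 peak lists of 10 columns with 1 list per library, so peaks were called by the authors on each library and not on pooled libraries. Each deposited peak has a start and an end, a score equal to 10 times the −log10 q and cut to a whole number, a fold enrichment over background (a linear ratio), and −log10 p and −log10 q values as the authors' peak caller gave them. The fold, score and −log10 values of a peak are the authors' own and were used here only to describe, rank or filter peaks within a list. The lowest −log10 q in a list lay between 3.003 and 3.034. Between 87 and 100 peak numbers per list were missing, and the deposited names state that blacklisted regions were removed. Absence of a peak means that none passed the caller's threshold, not that the site was closed.

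Read counts per library are not in the lists, so depth is unknown, and no counting interval was computed. A rough guide came from the fold column, whose values fall on steps of 1 read in 18.66% to 21.34% of peaks (within 0.01 of a whole step). If fold is pileup plus 1 over background plus 1 and the shortest peak equals the fragment length, both assumptions about the caller, relative depths were 1.047 and 1.011 in the 129O1 and EpiSC5 OPC libraries and 1.00 and 1.08 in the OL libraries.

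Genes and coordinates were taken from a RefSeq annotation of GRCm38.p6, the assembly named mm10, which gave 1 interval per gene for 21887 protein-coding genes. It held no strand, exon or transcript start, so the planned 2 kb upstream of the gene became 2 kb on both sides, and the planned promoter, exon and intron classes became sequence within 1 kb of either gene end, the rest of gene bodies and sequence outside protein-coding genes. Motif searches that had been planned need genome sequence and were not run here. The symbols of all fixed lists matched, 1 of them through its current name.

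Peak lists were compared by covered base pairs (Jaccard index), by overlap of at least 1 bp, and by merging overlapping or touching peaks of all 4 lists. For genes and for windows of 100 kb, the base pairs covered by peaks in each library were scaled to the mean list total, log2-transformed after adding 200 bp, and kept where the mean was at least 500 bp. OL was compared with OPC by limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) over all 4 libraries. A fold difference is on the log2(bp + 200) scale, which understates the change of genes with little coverage. The 18 gene lists were fixed before the data were examined and tested against all other tested genes by limma's camera with a preset correlation of 0.01, with an estimated correlation and with fry beside it. No list call made with the preset correlation held with the estimated correlation. That version of camera rests on the few residual degrees of freedom of 4 libraries, so a lost call does not show that correlation between genes made it. The estimate lay below the preset for the vascular (-0.0862), immature oligodendrocyte (-0.0159) and cytoskeleton (0.00745) lists, and above it for the other lists called. Fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, gave an adjusted p below 0.05 for 7 lists, 5 of them among the 9 that camera called. Random lists for comparison were matched on deciles of gene length and coverage. Intervals of differences between medians came from 2000 bootstrap resamples of genes or regions, which are not independent replicates.

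The genes named were set by a rule fixed before the data were examined. It takes Pdgfra, Cspg4 and Sox6, then the 12 genes in each direction with the largest difference among those past the threshold and alike in both lines, and up to 4 members of each list past the threshold (2 where none passed). For regions and windows it takes the 5 in each direction with the most covered sequence. A few genes and 1 window that this rule takes are not reported here. Tmem28 and the genes named in the closing part on the cell lines and on region-rich genes were chosen after their values were seen.

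The libraries share cell lines across groups, which pairs them. The deviations from the group means correlated at 0.287 between libraries of a line over genes and at 0.263 over windows. The main fit has no line term, and a fit with it was an alternative. The other alternatives were other pseudocounts, no filter, no scaling or median-of-ratios scaling, numbers of peaks, the 50% of peaks with the best q, lists of equal length, no variance trend, other gene regions and window sizes, autosomes alone, and leaving out each library. Peaks of 200 bp around the summit and genes that share no sequence with others were added after the data were seen. With 1 library per line and cell type, a difference between the lines in the OL against OPC change has no replicates and was not tested.

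The model was tested on simulated values with 200 changed features. For genes, 2% of changes of 0.5 on the log2 scale, 74% of changes of 1, 100% of changes of 1.5 and 96% of changes of 2 were recovered, with 2 false calls among 14343. For windows these shares were 2%, 68%, 84% and 86%, with 8 false calls among 16246. The noise was drawn from the model's own variance trend, independently for each library, with 17 prior degrees of freedom for genes and windows alike. The fitted value was 17 for genes but 7.39 for windows, and the correlation within a line was not simulated. The 200 changed features were also far fewer than the 2857 genes or 3713 windows called in the data. The cut-off set by the Benjamini-Hochberg adjustment depends on that number. Neither the recovered shares nor the few false calls therefore show how the model fares on these data. Covered base pairs of 500 genes were checked against bedtools 2.31.1, and none differed. Tables were handled in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.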

Results

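Chromatin accessibility was measured by Omni-ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse oligodendrocyte progenitor cells (OPCs) and in oligodendrocytes (OLs) sorted for the O1 antigen. Both cell types were grown from 2 lines of epiblast stem cells, pluripotent cells of the early embryo, named 129O1 and EpiSC5. Each cell type was represented by 1 library per line, so n = 2 in each group, and the question was which regions and genes differ in accessibility between the progenitor and the differentiated cell. The labels do not say whether the libraries came from independent differentiations, so the p-values measure the spread between these libraries. The deposited files are peak lists called for each library on mm10, without read counts. The OPC lists held 129534 peaks over 38.63 Mb in 129O1 and 125002 peaks over 44.11 Mb in EpiSC5. The OL lists held 127196 peaks over 35.02 Mb in 129O1 and 152595 peaks over 41.2 Mb in EpiSC5. Covered length was thus smaller in OLs than in OPCs of the same line, at 0.907 of the OPC value in 129O1 and 0.934 in EpiSC5, whereas the number of peaks was lower in OLs in 129O1 and higher in OLs in EpiSC5. Median peak widths were 201 and 237 bp in OPCs and 190 and 192 bp in OLs, in the order 129O1, EpiSC5. In the same order the shortest peaks were 78 and 100 bp in OPCs and 80 and 84 bp in OLs. The smallest listed width thus differed by library, and width and covered length may depend in part on it.

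Libraries of the same cell type shared more accessible sequence than libraries of the same cell line. The Jaccard index of covered base pairs was 0.577 between the OPC libraries and 0.653 between the OL libraries, against 0.412 between OPC and OL of 129O1 and 0.383 between OPC and OL of EpiSC5. Merging the lists gave 229743 regions, of which 55466 had a peak in all 4 libraries. Peaks in both OL lists and in neither OPC list marked 35878 regions, called OL-only regions here, and the converse marked 22713 OPC-only regions. The other ways of splitting the 4 libraries into pairs gave far fewer regions, 4800 for a split by cell line and 2297 for the crossed split. With 3 such splits the smallest permutation p is 0.333, so no significance is attached to these counts. Taking a peak in a single remaining library as sufficient raised the counts by construction. Without the 129O1 OL library 67626 regions were OL-only, and 47107 or 52734 were OPC-only without the 129O1 or the EpiSC5 OPC library. In the 50% of each list with the best q value, the counts fell to 18866 OL-only and 11796 OPC-only regions. Regions with a peak in 1 list alone numbered 26560 and 23661 for OPC and 7101 and 31135 for OL, in the order 129O1, EpiSC5. As the OL lists overlapped more than the OPC lists, the excess of OL-only regions need not mean that more sites were open in OLs.

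**Figure D1:**
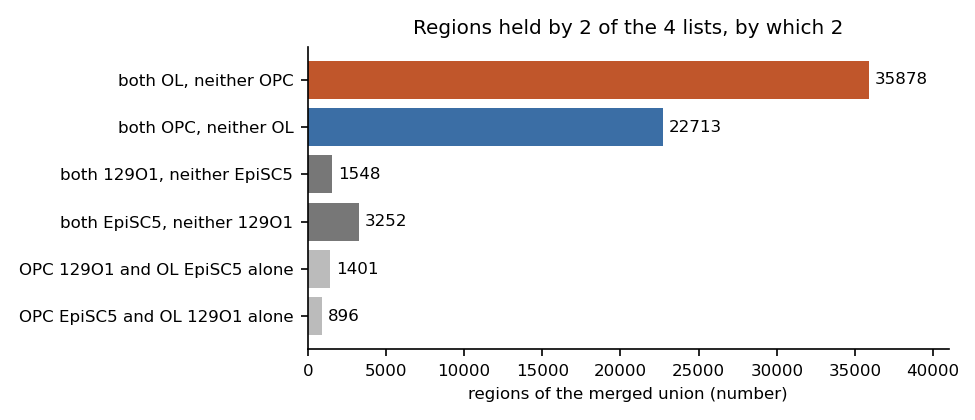
Number of regions of the merged union (x axis) that were held by exactly 2 of the 4 peak lists, for each of the 6 possible pairs. The OL pair shared 35878 regions and the OPC pair 22713, and the other 4 pairs shared between 896 and 3252.

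The OL-only regions lay mostly inside genes. The OL-only region with the most covered sequence was at chromosome 5, 30956323 to 30957893, in Preb, which encodes a regulator of vesicle budding at the endoplasmic reticulum. The next were in Atrnl1 (chromosome 19, 57634113 to 57635419), Tbccd1 (chromosome 16, 22830619 to 22831913), Lhcgr (chromosome 17, 88716983 to 88718156) and Chid1 (chromosome 7, 141505999 to 141507439). The largest OPC-only region was at chromosome 11, 119521833 to 119523616, 10368 bp from Endov. It was followed by a region at chromosome 16, 9993742 to 9995186, in Grin2a, an NMDA receptor subunit gene, by one 46035 bp from Bms1 (chromosome 6, 118335934 to 118337346), and by regions in Tenm4 (chromosome 7, 96209815 to 96211087) and Ctbp2 (chromosome 7, 133066798 to 133067963). Of the OL-only sequence, 61.9% fell in gene bodies beyond 1 kb from either gene end, 3.05% within 1 kb of a gene end and 35.03% outside protein-coding genes. For the OPC-only sequence these shares were 46.9%, 5.51% and 47.5%. Regions shared by all 4 libraries had 35.1% of their sequence near gene ends, where the chromosomes as a whole have 2.91%. In the rest of gene bodies these shares were 38.4% and 36.3%, so the OL-only and the OPC-only share both lay above them. Gene bodies took 40.1% and 40.5% of the covered sequence in the OPC lists and 44.5% and 46.0% in the OL lists, so the cell types differed by more than the lines did. No test was made of these shares.

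Pdgfra and Cspg4, which encode the CD140a and NG2 antigens used to purify the OPCs, did not pass the test, although both were higher in OLs in both lines. Pdgfra (chromosome 5, 75151322 to 75198206) had 2.33 ± 0.209 kb of peaks in OPCs and 2.82 ± 0.0259 kb in OLs (SD, n = 2, scaled covered kb), a log2 difference of 0.26 (limma adjusted p = 0.283). For Cspg4 (chromosome 9, 56865104 to 56899870) the means were 4.12 ± 0.147 and 4.39 ± 0.14 kb (log2 difference 0.09, adjusted p = 0.751), and without scaling its difference turned to -0.03. Sox6, a transcription factor gene of the progenitor state on chromosome 7 (115470872 to 116040776), had more peak coverage in OLs. Its mean was 16.3 ± 0.862 kb in OPCs and 23.5 ± 1.024 kb in OLs, a 1.43-fold difference (log2 0.52, SE 0.10, adjusted p = 0.00122). Peaks over the Sox6 region numbered 67 and 60 in the OPC libraries and 86 and 109 in the OL libraries, in the order 129O1, EpiSC5. Its body held 31 OL-only and 12 OPC-only regions. The Sox6 call was lost without scaling, with median-of-ratios scaling and when peaks were counted instead of base pairs.

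**Figure D2:**
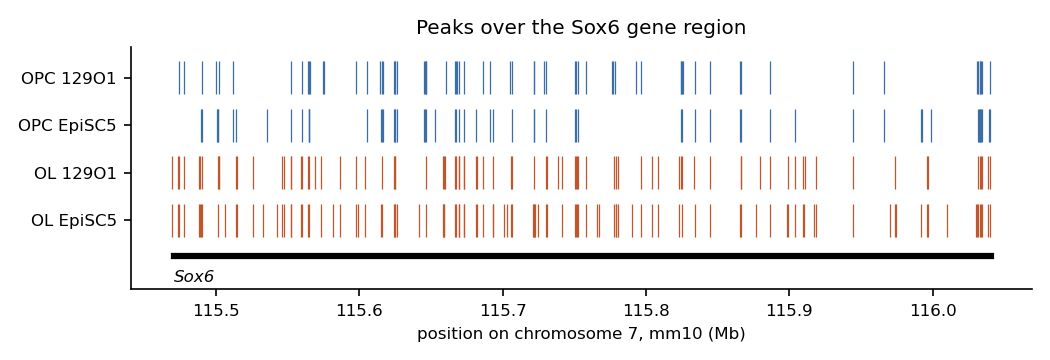
Positions of the peaks over Sox6 and the 2 kb on either side of it (x axis, Mb on chromosome 7, mm10) in each of the 4 libraries. Each vertical line is 1 peak, drawn at its midpoint with no height scale, and the black bar is the annotated gene. The OL libraries had 86 and 109 peaks and the OPC libraries 67 and 60.

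Across 14543 protein-coding genes with enough coverage, 2857 differed between OL and OPC at a limma adjusted p below 0.05, with 1602 higher and 1255 lower in OLs. Both lines moved in the fitted direction for 2856 of them, which the calling favours, as the fitted difference is the mean of the line differences. The exception was Tmem28, whose log2 difference was 0.01 in 129O1 and -1.72 in EpiSC5. Among the genes lower in OLs with the largest differences, the NMDA receptor gene Grin2a (chromosome 16, 9567901 to 9996083) had 3.04 ± 0.959 kb of peaks in OPCs and no listed peak in either OL library, and the potassium channel gene Kcnc4 had 1.31 ± 0.00408 kb and no listed peak. The AMPA receptor gene Gria1 fell from 2.47 ± 0.989 to 0.145 ± 0.0181 kb (7.48-fold lower in OLs, adjusted p = 9.79e-07). Also lower, by 4.43-fold to 6.62-fold, were Fam83a, the opioid receptor gene Oprm1 (76.2% of whose covered sequence also lies in other gene regions), the neural splicing regulator Srrm4, Cytip, the developmental regulator Trim71, Grxcr1, the growth factor gene Pdgfb and Best3. Higher in OLs were Pla2g4f, which had 0.0401 ± 0.0567 kb of peaks in OPCs and 1.78 ± 0.0288 kb in OLs (8.37-fold, adjusted p = 4.63e-06), and the immune receptor gene Tigit (0.102 ± 0.00607 and 2.05 ± 0.136 kb, 7.45-fold, adjusted p = 9.79e-07). Fold differences between 4.09 and 5.09 were found for Gm30083, Cdh17, Psma8, Marco, Gzmc, Smlr1, Atp13a5 and Piwil2. Ly6g6f had no listed peak in either OPC library and 1.18 ± 0.197 kb in OLs, all of it in sequence shared with neighbouring genes. Other gene regions also held 34.5% of the covered sequence of Tigit and 29.0% of that of Pla2g4f. For Atp13a5, Piwil2 and Gm30083 this share was 28.5%, 19.4% and 9.0%. These top genes have little coverage in the lower group, so their folds depend on the pseudocount of 200 bp.

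The number and balance of calls depended on the scaling and on the measure. Without scaling the median difference of all genes was -0.13 instead of -0.02 on the log2 scale, and 583 genes were called, 197 higher and 386 lower (33.8% higher, against 56.1%). Counting peaks in place of base pairs gave 531 calls, 71.2% of them higher. Without the 129O1 OL library the majority turned, with 1034 genes higher and 1197 lower. Of the 77 named genes past the threshold, 32 were still called without scaling and 31 by the number of peaks. Those lost without scaling include Mag, Mobp, Luzp2, Sema5a, Tnr, Vcan and Sox6. Tmem28 was singled out after its values were seen.

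**Figure D3:**
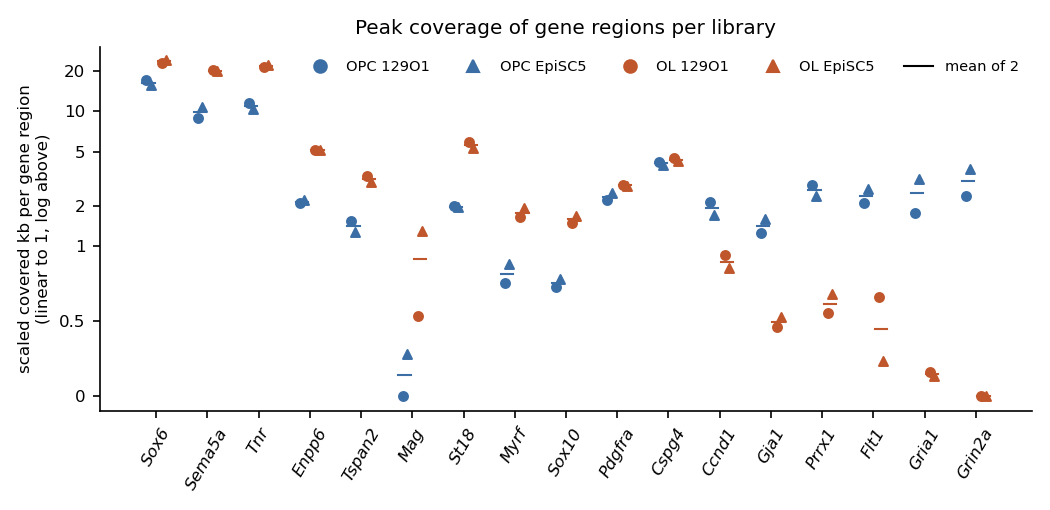
Scaled covered kb (y axis, linear up to 1 and logarithmic above) of 17 gene regions in each library. Blue marks OPC and orange OL, circles 129O1 and triangles EpiSC5, and the short line is the mean of 2. Sox6, Sema5a, Tnr, Enpp6 and St18 lie higher in both OL libraries, Gja1, Prrx1, Flt1 and Gria1 lie lower, Grin2a has no peak in OLs, and Pdgfra and Cspg4 lie slightly higher in OLs in both lines without passing the test.

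Part of the genes of the differentiating oligodendrocyte gained peak coverage. Of 28 tested genes on the immature oligodendrocyte list, 11 were higher in OLs and none lower, over all genes and adjusted over the list alone alike. The newly formed oligodendrocyte marker Enpp6 rose from 2.14 ± 0.059 to 5.18 ± 0.0215 kb (2.299-fold, adjusted p = 2.15e-05). Tmem163 was 2.05-fold and Dct 1.95-fold higher. The Tmem163 call was lost without scaling and the Enpp6 call by number of peaks, whereas Dct was called in both settings. On the mature oligodendrocyte and myelin list 7 of 32 tested genes were higher and 1 lower (8 and 1 adjusted over the list alone). The myelin genes Mag, Mobp and Tspan2 were 3.39-fold, 2.95-fold and 2.11-fold higher, and the exception, the cytokine gene Il33, was 2.98-fold lower. Mag had 0.139 ± 0.196 kb in OPCs and Mobp 0.493 ± 0.547 kb, so their folds depend on the added 200 bp. The Mobp difference was 2.54 in 129O1 and 0.58 in EpiSC5 (log2). The calls of Mag, Mobp and Tspan2 were lost by number of peaks and with peaks of 200 bp around the summit. Mag was also lost with 50 bp added, and Mobp with lists of equal length. The lists stood above the other genes by camera (adjusted p = 0.00551 for immature and 0.00589 for mature), and both adjusted p were 0.443 with an estimated correlation. Their median log2 differences of 0.20 and 0.21 lay at percentiles 97.9 and 99.96 of 10000 random lists matched on gene length and coverage. The mature list gave adjusted p = 0.0657 without the 129O1 OPC library, and the Il33 call was lost without the 129O1 OL library (adjusted p = 0.117) and with the cell line as a block (adjusted p = 0.0897).

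Several genes of the OPC identity list were also more covered in OLs. Of 29 tested members 7 were higher and 2 lower (9 and 3 adjusted over the list alone). Luzp2 rose from 1.38 ± 0.225 to 5.73 ± 2.12 kb (3.65-fold), the semaphorin gene Sema5a from 9.85 ± 1.39 to 20.1 ± 0.406 kb (2.03-fold), and the extracellular matrix genes Tnr and Vcan were 1.96-fold and 1.59-fold higher. Camera gave adjusted p = 0.00959, and adjusted p = 0.443 with an estimated correlation. The list call was lost without scaling (adjusted p = 0.112), and the median difference of 0.09 lay at percentile 76.8 of the matched random lists. On the list of cytoskeleton and adhesion genes 9 of 38 were higher and 4 lower (12 and 6 adjusted over the list alone). Sh3gl3 was 2.16-fold, the choline transporter gene Slc44a1 1.95-fold, the tubulin gene Tubb4a 1.81-fold and the microtubule-associated Map7 1.74-fold higher. Camera gave adjusted p = 0.0131 for this list, and 0.443 with an estimated correlation. Its median of 0.16 lay at percentile 82.0 of matched lists, and the call was lost without the EpiSC5 OL library (adjusted p = 0.0719). The Tubb4a call was lost without the 129O1 OL library (adjusted p = 0.0742).

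Transcription factors of the lineage moved both ways, with 8 of 29 higher and 4 lower over all genes and adjusted over the list alone (camera adjusted p = 0.265). St18 rose from 1.96 ± 0.0283 to 5.62 ± 0.375 kb (2.69-fold, adjusted p = 4.63e-06), and Zfp488, the myelin regulatory factor gene Myrf and Sox10 were 2.13-fold, 1.94-fold and 1.86-fold higher. The calls of Zfp488, Myrf and Sox10 did not hold without scaling.

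**Figure D4:**
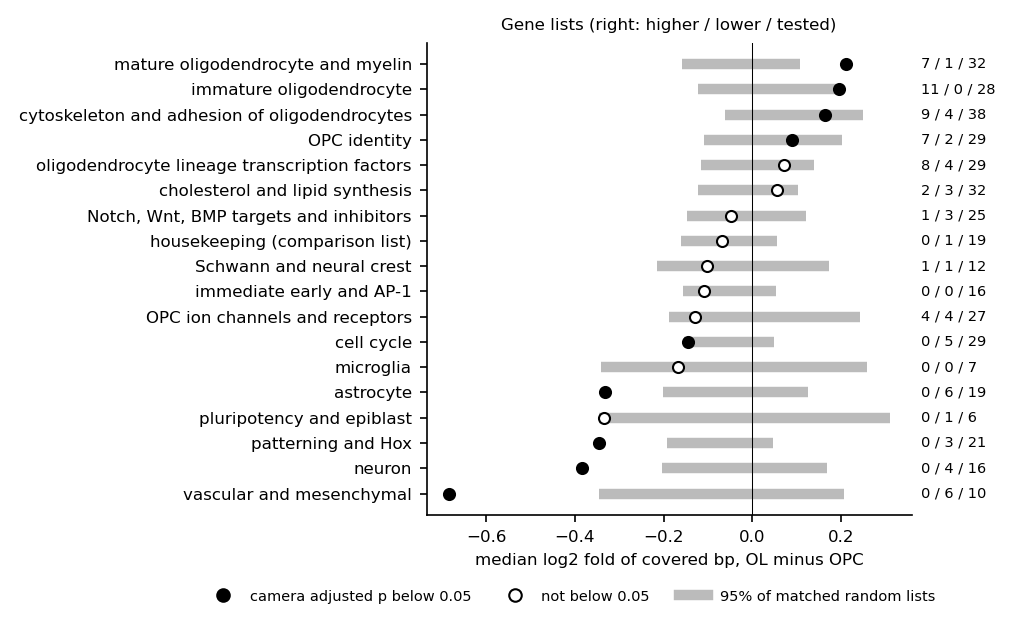
Median log2 difference of covered base pairs, OL minus OPC (x axis), for each of the 18 gene lists (y axis). Filled points have a camera adjusted p below 0.05, grey bars span the central 95% of 10000 random lists matched on gene length and coverage, and the figures at the right give members higher, lower and tested. The vascular, neuron, patterning and astrocyte lists lie left of their bars, and the mature and immature oligodendrocyte lists lie at or beyond the right end of theirs.

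Several vascular, astrocyte and neuron markers fell in OLs. On the vascular and mesenchymal list 6 of 10 tested genes were lower and none higher (7 lower adjusted over the list alone). The VEGF receptor gene Flt1 fell from 2.37 ± 0.383 to 0.448 ± 0.306 kb (4.19-fold lower in OLs, adjusted p = 1.53e-05) and the mesenchymal transcription factor gene Prrx1 from 2.59 ± 0.331 to 0.616 ± 0.0916 kb (3.42-fold, adjusted p = 3.18e-06). Acta2, which encodes smooth muscle actin, was 2.62-fold and the pericyte marker Pdgfrb 1.77-fold lower. On the astrocyte list 6 of 19 were lower and none higher (9 lower adjusted over the list alone), among them the gap junction gene Gja1 (2.33-fold lower), Ranbp3l (2.11-fold), the glutamate transporter gene Slc1a3 (1.46-fold) and Mlc1 (1.45-fold). The neuron list had 4 of 16 lower and none higher (5 lower adjusted over the list alone), with Eomes 3.15-fold, Gad2 1.68-fold, Snap25 1.53-fold and Map2 1.30-fold lower. Camera gave adjusted p = 0.000251 for the vascular, 0.00551 for the astrocyte and 0.0132 for the neuron list, and 0.443 for each with an estimated correlation. The astrocyte call was lost without the EpiSC5 OPC library (adjusted p = 0.0872), and the neuron call without the EpiSC5 OPC library (adjusted p = 0.117) or the EpiSC5 OL library (adjusted p = 0.0706). The calls of Slc1a3 and Map2 were lost without either OL library (adjusted p up to 0.0676 and 0.190), Map2 also without the EpiSC5 OPC library and with the cell line as a block (adjusted p = 0.0539). Gad2 was lost without the 129O1 OPC or the EpiSC5 OL library (up to 0.221), and Snap25 without either EpiSC5 library (up to 0.0845). Mlc1 was lost without any library but the EpiSC5 OL one (up to 0.193), and Pdgfrb without any but the 129O1 OL one (up to 0.188).

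A minority of cell cycle and patterning genes fell. Of 29 tested cell cycle genes 5 were lower and none higher, over all genes and adjusted over the list alone alike. Tyms, which encodes thymidylate synthase, fell from 1.38 ± 0.215 to 0.589 ± 0.0233 kb (1.99-fold lower in OLs, adjusted p = 0.00119), and the cyclin gene Ccnd1, the kinase gene Plk1 and Ccnd2 were 1.92-fold, 1.81-fold and 1.77-fold lower. On the list of Hox and other patterning genes 3 of 21 were lower and none higher (2 lower adjusted over the list alone). Emx2 was 2.61-fold lower, Hoxb4 1.92-fold and Hoxb6 1.89-fold, and the covered sequence of Hoxb4 lies wholly and that of Hoxb6 partly (43.2%) in the regions of other genes. Camera gave adjusted p = 0.00716 for the cell cycle and 0.00551 for the patterning list, and 0.557 and 0.443 with an estimated correlation. The median of the cell cycle list, -0.15, lay at percentile 3.62 of the matched random lists, and that of the patterning list, -0.35, at percentile 0.01. Without the EpiSC5 OL library the patterning list gave adjusted p = 0.122 and Ccnd2 0.0917. The Plk1 call was lost without the EpiSC5 OPC library (adjusted p = 0.0606), and those of Hoxb4 and Hoxb6 without the 129O1 OPC or the EpiSC5 OL library, with adjusted p up to 0.359 and 0.341. Hoxb6 was also lost with the cell line as a block (adjusted p = 0.0781). The calls of Emx2, Hoxb4 and Hoxb6 were all lost without scaling, with median-of-ratios scaling and by number of peaks. Nor did they hold with peaks of 200 bp around the summit or with 20 kb on either side. The Emx2 difference was -0.70 in 129O1 and -2.07 in EpiSC5 on the log2 scale.

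The remaining lists did not pass the threshold by camera, which does not show that they were unchanged. The median log2 difference of the 6 tested pluripotency and epiblast genes was -0.33, as was that of the astrocyte list. It lay at percentile 2.85 of matched random lists. Of 32 cholesterol and lipid synthesis genes 2 were higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.566), with Acaca 1.61-fold higher and Fdft1 1.77-fold lower. Among 25 Notch, Wnt and BMP targets and inhibitors of differentiation, Bmpr1a was 1.349-fold higher and Jag1, Smad6 and Id1 were 2.004-fold, 1.80-fold and 1.53-fold lower (1 and 3 members adjusted over the list alone; adjusted p = 0.166). Of 27 OPC ion channel and receptor genes 4 were higher and 4 lower (4 and 5 adjusted over the list alone; adjusted p = 0.273, and 0.0482 without the 129O1 OPC library). Beyond Grin2a and Gria1 these included the calcium channel gene Cacna1a, 1.76-fold lower, and the kainate receptor gene Grik2, 1.53-fold higher. None of 16 immediate early genes passed the threshold (adjusted p = 0.274), with differences of -0.40 for Egr3 and -0.32 for Nr4a1 on the log2 scale. Nor did any of 7 microglial genes (adjusted p = 0.6), where P2ry12 differed by -0.51 and Tmem119 by 0.43. On the Schwann and neural crest list Mitf was 1.61-fold higher and Pou3f1 1.58-fold lower among 12 tested (adjusted p = 0.799), the latter with adjusted p = 0.0504 without the EpiSC5 OL library and turned to 0.13 on the log2 scale, not called, by the number of peaks. Eomes was the 1 lower member among 6 pluripotency and epiblast genes, 2 adjusted over the list alone (adjusted p = 0.0958, and 0.0233 without the 129O1 OPC library). Among 19 housekeeping genes Gapdh alone was called, 1.503-fold lower, also adjusted over the list alone (list adjusted p = 0.458). The calls of Gapdh and Id1 were lost without any library but the 129O1 OL one (adjusted p up to 0.111 and 0.190), and Bmpr1a without any but the 129O1 OPC one (up to 0.219) and with the cell line as a block (adjusted p = 0.0598).

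Longer genes gained coverage relative to shorter ones. In the shortest tertile of the tested genes 118 were higher and 255 lower in OLs, in the middle tertile 478 and 368, and in the longest tertile, above 46385 bp, 1006 and 632. The median log2 difference from the shortest to the longest tertile was -0.03, 0.02 and 0.07 in 129O1 and -0.12, -0.04 and 0.08 in EpiSC5. Spearman's correlation between gene length and the difference was 0.123 in 129O1 and 0.207 in EpiSC5, across genes, which are not independent replicates. Without scaling the order of the tertiles was kept, but the longest tertile lay below 0 in both lines, at -0.05 and -0.01, so the sign for long genes rests on the scaling to equal covered length.

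**Figure D5:**
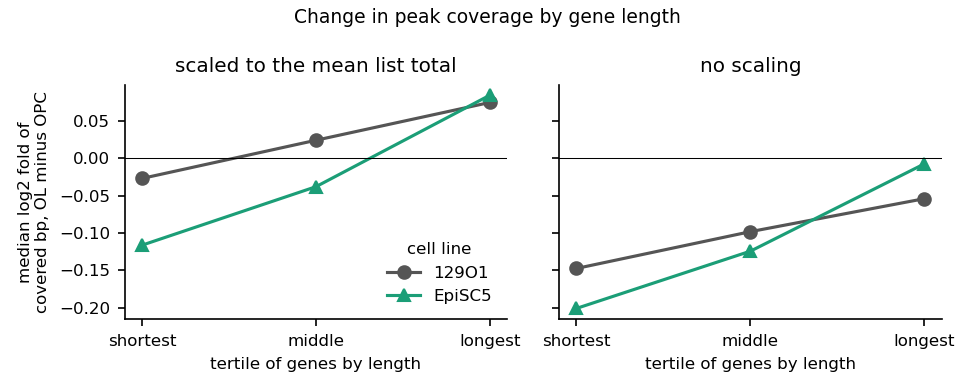
Median log2 difference of covered base pairs, OL minus OPC (y axis), in tertiles of gene length (x axis), for 129O1 (circles) and EpiSC5 (triangles), with scaling to the mean list total at the left and without scaling at the right. In both panels the longest genes lie above the shortest in each line.

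In windows of 100 kb, which need no gene annotation, 3713 of 16446 differed at a limma adjusted p below 0.05, 1932 higher and 1781 lower in OLs. The higher window with the most covered sequence (chromosome 15, 79100001 to 79200000) holds Sox10, Polr2f and Micall1 and had 7.02 ± 0.133 kb of peaks in OPCs and 9.38 ± 0.403 kb in OLs (log2 0.41, adjusted p = 0.0156). The adjoining window, 79200001 to 79300000, with Pick1 and Pla2g6 was also among the 5 most covered (log2 0.45, adjusted p = 0.0265). Also among them were windows on chromosome 11 (118200001 to 118300000, with Cyth1 and Usp36) and chromosome 2 (153400001 to 153500000, with Asxl1 and Nol4l). Among the lower windows the most covered was at chromosome 18, 35800001 to 35900000, with Cxxc5 and Ube2d2a, at 10.7 ± 0.756 kb in OPCs and 8.02 ± 0.478 kb in OLs (log2 -0.41, adjusted p = 0.0179). It was followed by windows at Irf2bpl (chromosome 12, 86800001 to 86900000), Klhl9 (chromosome 4, 88700001 to 88800000), Hdac5 (chromosome 11, 102200001 to 102300000) and Ahdc1 (chromosome 4, 133000001 to 133100000). Without scaling 1955 windows were called, 34.8% of them higher, against 52.0%. Leaving out the 129O1 or the EpiSC5 OL library left 1343 and 1987 calls, 39.1% and 39.9% of them higher. Leaving out the 129O1 or the EpiSC5 OPC library left 3500 and 4108, 57.9% and 57.5% of them higher. With the cell line as a block 5208 windows were called.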

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

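The tests of list length for longer genes, of peak width, of a lower share of the main cell type, of the fold and of the pileup of shared peaks were chosen after the result was seen. The cell lines differed in direction for the number of peaks, which changed by -2338 from OPC to OL in 129O1 and by 27593 in EpiSC5. They also differed for the median log2 difference of the middle tertile of gene length, 0.0237 in 129O1 and -0.0383 in EpiSC5. Neither difference was tested, since each line has 1 library per cell type.

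Longer genes and gene bodies held relatively more of the peak coverage in OLs. With lists of equal length, the gene body share of OL-only sequence still exceeded that of OPC-only sequence by 14.87 percentage points, which argues against list length. The longest tertile still lay above the shortest by 0.1018 on the log2 scale in 129O1, whose full lists differed little in length. In EpiSC5, whose full lists differed more, this difference fell from 0.2002 to 0.1422 (0.123 to 0.16). This argues against list length as the whole cause there and leaves it open for part. In 129O1 the 50% of peaks with the best q gave 0.0430 (0.0266 to 0.0601). With 200 bp around each summit, the longest tertile lay above the shortest by 0.1366 on the log2 scale in EpiSC5 (95% interval over resampled genes 0.0830 to 0.187), which argues against peak width as the whole cause there. In 129O1 the difference was 0.07066 (0.00733 to 0.0981), and 0.0337 by number of peaks (0.00427 to 0.0946), against 0.101 with full widths, so peak width stays open as a cause of much of it. With fixed width fewer genes passed the filter, and the longest tertile began at 67841 bp instead of 46385 bp. The fixed-width and full-width differences are thus not of the same genes, and their gap cannot be put down to width alone. The immature and mature oligodendrocyte genes of the longest tertile lay at percentile 77.92 of random lists, a value under 90 having been set to count against them, but these lists were matched on length and so hold the trend themselves, which leaves these genes open, as are differences in read depth.

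On the vascular, astrocyte and neuron lists 6, 6 and 4 genes were called lower in OLs and none higher, although leaving out the 129O1 OPC or the 129O1 OL library gave 1 higher vascular gene, and no filter or 20 kb on either side 1 higher astrocyte gene. Their medians lay at percentiles 0.04, 0.05 and 0.04 of lists matched on gene length and coverage, which argues against these properties. A lower share of the main cell type in the OPC cultures was predicted to raise the markers of all other types alike. The medians of the 5 lists of other cell types spread more than by permutation of their members (p = 0.01699), which counts against such an even rise. Other types need not be present in equal shares, and genes are not independent, so the spread does not exclude a lower share of the main type. Among vascular genes below the coverage filter, Cdh5, Tagln, Rgs5 and Col3a1 had peaks in all 4 libraries, Cdh5 637 and 646 bp in OPCs against 139 and 394 bp in OLs, whereas Cldn5 had none in any and Lum 140 bp in 1 OPC library. Cells of other types in the OPC cultures, which were sorted before expansion, and a change within the lineage both stay open, as no test here separates them.

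Chromosomes 15 and 17 took different shares of the peaks in the cell lines, EpiSC5 over 129O1 being 1.10 in OPC and 1.11 in OL for chromosome 15, and 0.917 and 0.869 for chromosome 17. With lists of equal length the chromosome 15 ratio was still at least 1.097, which argues against list length. At least 90% of 10 Mb bins on chromosome 17 lay below the median bin of the other autosomes in each cell type, as a lower copy number in EpiSC5 could give, and on chromosome 15 72.73% in OPC and 90.91% in OL lay above, where other autosomes reached 76.92% and 77.78%. The fold of shared peaks went against copy number on both chromosomes, at -0.08 in OPC and -0.06084 in OL on chromosome 15 and 0.05 and 0.07 on chromosome 17, but fold is relative to a background that was the fixed genome-wide one for at most 21.34% of peaks. Over shared regions with that fixed background in both lines, the log2 difference was 0.07717 in OPC and 0.113 in OL on chromosome 15 and -0.01594 and -0.0931 on chromosome 17, with intervals that reach 0 except in OL on chromosome 15, so the pileup does not settle copy number for either chromosome.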

How the results depend on the processing

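Fixed 200 bp peaks around summits, genes whose region overlaps no other and lists of equal length for the trend with gene length were chosen after the data were seen, the other settings before. In the 50% of each list with the best q 18866 regions were OL-only and 11796 OPC-only. Leaving out 1 library gave 39683 to 67626 and 27300 to 52734. The cause of the changes below was not tested, except that fewer peaks, genes or libraries make some calls impossible. With 1 library left in a group, it is assumed to vary like the other group.

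Genes called numbered 583 without scaling, 531 by number of peaks, 1632 with the better 50% of peaks, 742 with fixed width and 1311 without overlapping genes (2005 to 2300 without 1 library). Windows called numbered 1955 without scaling, 1362 by number of peaks, 1739 with the better 50%, 2088 without the variance trend and 1488 with fixed width (1343 to 4108 without 1 library). With the cell line as a replicate block 2908 genes and 5208 windows were called. The block ended the calls of Bmpr1a, Hoxb6, Il33 and Map2 and changed no other call of a named gene or, by camera, of a list. By fry, of 7 lists called, only the vascular one was called with the block (adjusted p = 0.0403). Cspg4 turned to -0.026 without scaling and -0.0394 with fixed width, Pou3f1 to 0.13 by number of peaks and Gapdh to 0.0069 with 20 kb on either side (log2).

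Of 9 lists called, 4 were called by number of peaks, 5 in gene bodies alone, and 0 with fixed width or with an estimated correlation (adjusted p = 0.443 for each but the cell cycle, 0.557). The test with an estimated correlation has few degrees of freedom here, so its losses cannot be read as an effect of correlation. With fixed width the adjusted p was 0.201 for OPC identity, the cytoskeleton and neurons, 0.160 for immature and 0.120 for mature oligodendrocytes, 0.133 for the cell cycle, 0.1355 for patterning, 0.0785 for astrocytes and 0.0717 for vascular genes, and 0.754 for the lineage transcription factors and Schwann genes, both reversed. By number of peaks it was 0.1655 for OPC identity and patterning, 0.3055 for the cell cycle and neurons, 0.0893 for the cytoskeleton and 0.585 for Schwann genes, reversed. With the better 50% of peaks it was 0.0794 for immature and 0.0764 for mature oligodendrocytes, 0.0904 for the cytoskeleton and patterning, and 0.0454 for Notch, Wnt and BMP targets, newly called. In gene bodies alone it was 0.0560 for immature oligodendrocytes and neurons, 0.140 for mature ones and 0.114 for the cytoskeleton. OPC identity had 0.112 without scaling, 0.0642 with median-of-ratios scaling and 0.0553 with 20 kb on either side, where neurons had 0.119. Without overlapping genes it was 0.0551 for the cytoskeleton and astrocytes and 0.0954 for patterning. Microglial genes reversed without the filter (0.895). Fry gave 0.0433 for the lineage transcription factors and for Notch, Wnt and BMP targets, 0.129 for mature oligodendrocytes, 0.137 for the cell cycle, 0.386 for patterning and 0.127 for neurons.

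Leaving out 1 library, the adjusted p ran from 0.000198 to 0.0657 for mature oligodendrocytes, 0.0482 to 0.342 for OPC ion channels, 0.00528 to 0.0719 for the cytoskeleton, 6.23e-06 to 0.122 for patterning, 0.00233 to 0.0872 for astrocytes, 0.00827 to 0.117 for neurons, 0.630 to 0.887 for Schwann genes, 0.0233 to 0.260 for pluripotency and 0.229 to 0.995 for housekeeping genes. Schwann genes reversed without the EpiSC5 OPC library (0.807) or the 129O1 OL library (0.789), and housekeeping genes without the EpiSC5 OL library.

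With at least 50% of a peak covered, libraries of the same line shared 49.41% of peaks and those sharing neither 48.62%. Covered length in OLs was 0.899 of that in OPCs with the better 50% of peaks. The shortest tertile's median was -0.17 without scaling and -0.000265 with fixed width. The longest tertile's was -0.031 without scaling, reversed, 0.088 by number of peaks, 0.07 with the better 50% and 0.10 with fixed width. With the better 50% or fixed width the tertiles hold other genes, since the coverage filter was applied anew. With gene ends of 2 kb, gene bodies held 60.09% of OL-only and 44.79% of OPC-only sequence. The planned motif alternatives were not run. Read depth is not recorded in the lists, so its effect on the number of peaks was not separated from that of cell type.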

Other observations

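The genes and lists of this part were chosen after their values were seen. Genes with the most regions of 1 cell type in their bodies were long, whichever the cell type. The count was not divided by gene length, so the measure itself favours long genes. Csmd1 held 60 OL-only and 7 OPC-only regions, Lsamp 57 and 12, Opcml 51 and 13, Astn2 48 and 9, and the semaphorin gene Sema5a 38 and 5. Others went the opposite way, with 13 OL-only and 26 OPC-only regions in Arhgap26, 10 and 20 in the transcription factor gene Nfia, 8 and 20 in Rbms3 and 6 and 18 in Ank2. These counts were not tested.

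Between the cell lines, 4 of 14543 genes differed at a limma adjusted p below 0.05, and 1668 at an unadjusted p below 0.05. Zfp993, Rbfox1 and Wdfy4 were higher in EpiSC5 by 2.12, 2.58 and 1.74 on the log2 scale, and for Slitrk5 the difference was -2.68, alike in direction in both cell types. The patterning and Hox list was lower in EpiSC5 (camera adjusted p = 0.0268, and adjusted p = 0.724 with an estimated correlation). Hoxd3 and Hoxb8 differed by -1.19 and -1.25, with adjusted p = 0.0765 and 0.0915. The housekeeping list was also lower (adjusted p = 0.0268), and the mature oligodendrocyte list stood higher by camera (adjusted p = 0.00870) with a median of -0.003. Camera compares a list with the other genes and not with 0. In both cell types 7 members of the mature list were higher and 9 lower in EpiSC5. For the housekeeping and the mature list the adjusted p was 0.724 with an estimated correlation.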
